A study of Arabidopsis thaliana and Arabidopsis thaliana
Cuscuta pentagona and Cuscuta pentagona with 6 samples.

How the data were processed

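Small RNA was sequenced from 3 kinds of tissue of the parasitic plant dodder growing on *Arabidopsis thaliana* ecotype Columbia, with 2 biological replicates of each per the series' design text. Host stem and parasite stem were each taken about 4 cm above the site of attachment, and interface is the site where the parasite's haustorium, its feeding organ, enters the host stem, so it holds tissue of both plants. The labels name the parasite *Cuscuta pentagona* in the sample descriptions and *C. campestris* in the series title, and it is called dodder or the parasite here. Libraries were made with an indexed Illumina small RNA kit per the labels.

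The authors deposited 2 tables of raw, whole-number counts with 1 column per library. The host table lists 36918 loci of the *Arabidopsis* nuclear chromosomes by chromosome, start and end. The parasite table lists 29988 clusters of sequences, each with a number and a head sequence of 20 to 24 nt. The submitters' processing notes name cutadapt 1.9.1, Bowtie 1.1.2 and the build TAIR10, with no role or order. The way in which clusters were formed, the counter, the treatment of reads that fit several places and the rule that assigned a read to a species are not given in the sources used here. Near-identical miRNA gene copies may therefore share reads, and the strand of the counted reads is unknown, so overlapping and antisense genes were not told apart. No parasite genome was used here, and clusters have no genome position.

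Host loci were annotated with the gene models of TAIR10.1, whose 5 nuclear chromosomes hold every locus within their lengths. A locus took the first class it overlapped by at least 1 base, in the order miRNA gene, tRNA, rRNA, snoRNA or snRNA, transposon, protein-coding, other annotated, none. Plastid and mitochondrial loci were not analysed here. The annotation has few transposon features and no 25S rRNA gene, so an alternative added after the data were seen extended the rRNA class to 6000 bases from the start of each 18S gene. Parasite heads were aligned to TAIR10.1 with bwa 0.7.19 allowing 2 mismatches. Of the heads, 19 matched exactly, 284 with 1 mismatch and 1649 with 2, as if most exact matches had been given to the host table.

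Interface was compared with host stem in the host table and with parasite stem in the parasite table, 2 libraries against 2, with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3). Loci were kept by filterByExpr with its default minimum count of 10, TMM factors came from the same table alone, and loci were called at a Benjamini-Hochberg FDR under 0.05. Values per library are counts scaled to a common library size as CPM of the loci tested after TMM scaling, and errors of log2 fold changes are standard errors (SE) from the fit. The gene lists, the tests of both comparisons, of the lists and of the locus classes, the named-locus rule and the alternatives listed at the end were fixed before the data were examined. The exceptions, added after the values were seen, were a list of all miRNA genes, the tests of parasite clusters by head length and by match to *Arabidopsis*, the duplex search, the alternatives said to be added, and the tests of explanations in the closing section. The search for target sites was set down before its result was seen, though the genes it was run on were already known to have risen. Lists were tested with fry (limma 3.58.1) on log2 CPM with a prior count of 2, and with camera with a preset and with an estimated correlation. Classes were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the classes and directions of each family. Heads of 21 or 22 nt called higher were searched against the longest coding transcript of each gene with a tested protein-coding locus. A site scored 1 for a mismatch and 0.5 for a G:U pair, with a weight of 2 at positions 2 to 13 from the 5′ end of the head, and a score of 4 or less was kept. The control was 10000 random draws of heads that were not called. Duplex partners were heads of the same length that paired with 3′ overhangs of 2 nt at a score of 4.5 or less, with reversed sequences as the control. Clusters with host stem counts of at least 10% of their interface counts were left out of both searches. A head was set beside an *Arabidopsis* miRNA at up to 2 mismatches. A planned test of whether called parasite loci lie on shared sequences was not run, since the clusters carry no position. The list of sulfate miRNAs (MIR395) had no tested locus and the list of silencing genes had 1.

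The loci named in the text were drawn from, per comparison, the 8 with the largest fold change in each direction among called loci whose libraries of both groups did not overlap and whose higher group averaged at least 20 counts, and the 6 with the highest mean CPM, and in the host comparison also up to 4 members of each list by p and each tested locus of the study's own target list. Not each of the list members drawn is named. Other loci and clusters are named as chosen after their values were seen.

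Depth per library, as the sum of both tables, ran from 1340574 to 2061510 counts. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 was bounded at 3 counts over the group. Intervals and floors cover counting error only, since reads carry no molecular identifiers. The test was checked on simulated counts for the real loci with 200 loci changed. In the host comparison, simulated over 8878 loci, 88.9% of tested 4-fold changes and 27.8% of tested 2-fold changes were recovered, with 1 false call. In the parasite comparison, simulated over 22024 clusters, the shares were 85.5% and 6.98%, with 1 false call. The replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom between 1.55 and 5.62 over loci with at least 10 counts, so each library counted as 1 replicate.

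Alternatives were DESeq2 size factors in edgeR, table totals, the summed totals of both tables as library size, the DESeq2 1.42.0 Wald test, no low-count filter, a minimum count of 50, a fit over all 6 libraries, a test against a 2-fold change (glmTreat), an FDR under 0.01, leaving out loci whose counts in the stem of the other species reached 10% of their interface counts, a replicate block, and leaving out each library in turn. An alternative added later left out parasite clusters whose heads lie within 2 mismatches of *Arabidopsis*. Tables, permutation tests and plots were made with Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9.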

Results

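Small RNA reads were counted in 6 libraries, 2 of host stem, 2 of interface and 2 of parasite stem, at 36918 loci of *Arabidopsis* and in 29988 clusters of parasite sequences. The sum of both tables was 1659530 and 1471249 counts in host stem replicates 1 and 2, 2061510 and 1960245 counts in the interface, and 1340574 and 1579148 counts in parasite stem. The interface holds tissue of both plants, so the first question was how much of each library came from each species.

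In host stem, 98.5% ± 0.0174 (SD, n = 2) of the summed counts lay in the host table. The interface had 34.2% ± 0.877 (SD, n = 2) and parasite stem had 28.0% ± 0.978 (SD, n = 2). The exact 95% binomial intervals of single libraries, which cover counting error only, were 34.8% to 34.9% and 33.5% to 33.6% in the interface. They were 28.6% to 28.8% and 27.3% to 27.4% in parasite stem. No test of these shares was made, and an exact permutation test of 2 libraries against 2 could not go below p = 1/3. Of the host-table counts of parasite stem, 88.2% lay at miRNA genes, whose mature sequences are conserved between plants, and 5.18% at loci with no annotation. The locus of MIR166a, a miRNA that represses HD-ZIP III transcription factors (chromosome 2, 19176075 to 19176264, TAIR10), alone had 309857 and 340656 counts in the parasite stem libraries. Without the 10 loci with the most counts in each table, the host share was 98.3% in host stem, 26.2% in the interface and 5.96% in parasite stem. Interface counts at conserved miRNA loci therefore cannot be assigned to 1 species.

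**Figure D1:**
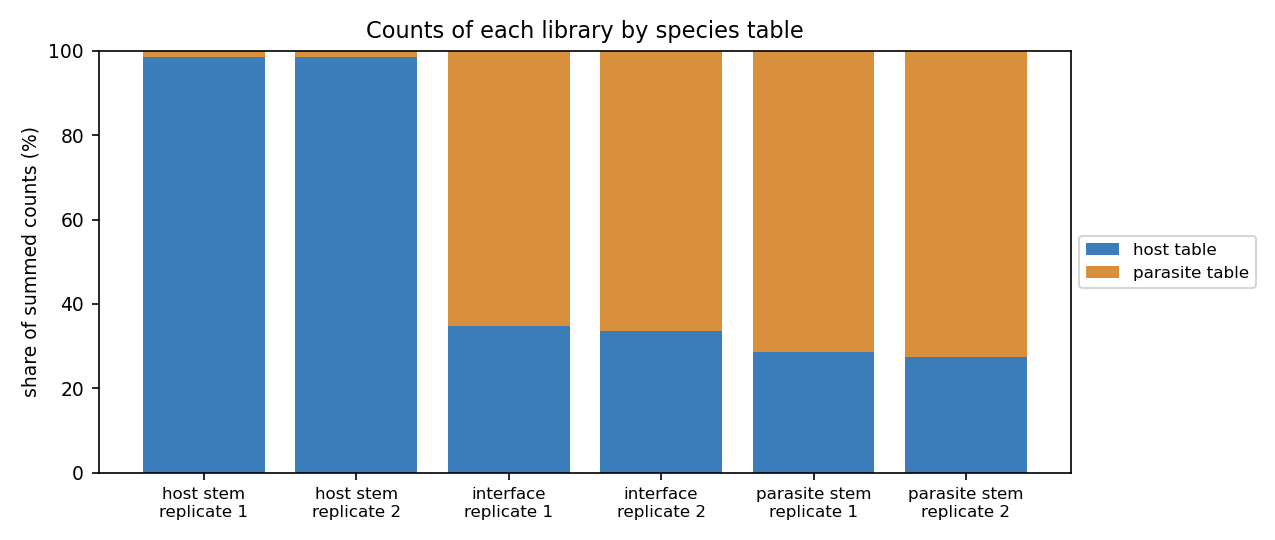
Share of the summed counts of each library (percent) that lay in the host table (blue) and in the parasite table (orange), for both replicates of host stem, interface and parasite stem. The host share was near 98.5% in host stem, 34.2% in the interface and 28.0% in parasite stem.

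The comparison of interface with host stem asks which *Arabidopsis* small RNA loci change where the parasite attaches. Small RNAs from coding exons of the auxin receptor genes TIR1, AFB2 and AFB3, the immune kinase gene BIK1, the phloem protein gene SEOR1 and the transcription factor gene HSFB4 were higher at the interface at all 15 tested loci. The main locus of TIR1 rose from 31.8 ± 2.41 to 1261 ± 304 CPM (SD, n = 2). Of the miRNAs of phosphate shortage 3 of 3 loci were also higher, and of those of copper shortage 3 of 5, though the copper median fell to -0.24 with the summed totals. Lower calls covered 9 of 20 loci of Brassicaceae-specific miRNAs, 4 of 6 of miRNAs of the silencing pathway and 6 of 11 of PPR siRNAs. With an estimated correlation 0 of 16 lists were called. Of 8878 loci tested, 194 were called higher and 394 lower. Among the 6 loci with the highest mean CPM, 2 in AT3G06365 moved by -1.40 ± 0.21 and -0.89 ± 0.20 and MIR158a by -1.22 ± 0.21 (SE, n = 2 per group). The AT3G06365 loci lie near rRNA loci on chromosome 3 and may be rRNA sequence. The others of these 6 are given below.

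The list of 6 genes named by the study had 15 tested loci, of which 15 were higher, 0 lower and 0 not called, and the numbers adjusted over the list alone were the same. The list was chosen on material that includes these samples, so its direction is not independent evidence. Its median log2 fold change was 5.15, and fry's directional test, which asks whether members move 1 way and not whether they differ from other loci, gave an adjusted p = 0.00434 (adjusted p = 0.122 with an estimated correlation). The auxin receptor list, whose 8 tested loci also lie in the study's list, had 8 higher, 0 lower and 0 not called, with 8 higher when adjusted over the list alone. Its median was 4.84, with an adjusted p = 0.00434 (adjusted p = 0.122 with an estimated correlation). TIR1, an F-box auxin receptor, had loci in its coding exons on chromosome 3 (TAIR10) at 23275713 to 23276156, 23274485 to 23274987 and 23273224 to 23274305. Their log2 fold changes were 5.30 ± 0.21, 4.79 ± 0.21 and 4.27 ± 0.19 (SE, n = 2 per group), and the first had an adjusted p = 7.81e-18 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its raw counts were 48 and 46 in host stem and 664 and 845 in the interface, against 3 and 5 in parasite stem. AFB3, of the same receptor family, rose by 6.11 ± 0.25 at chromosome 1, 4369754 to 4370752, and by 2.65 ± 0.20 at 4368688 to 4369650, a locus that overlaps a second gene. AFB2 rose by 5.15 ± 0.43, 4.90 ± 0.44 and 1.77 ± 0.30 at chromosome 3, 9869105 to 9869599, 9868422 to 9868868 and 9869687 to 9870660, all in coding exons.

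BIK1, a receptor-like cytoplasmic kinase of immune signalling, had 4 loci in its coding exons on chromosome 2, at 16533169 to 16533795, 16532733 to 16532875, 16532952 to 16533076 and 16532543 to 16532651. They rose by 6.23 ± 0.25, 6.17 ± 0.36, 5.27 ± 0.26 and 3.83 ± 0.70, and the last lost its call without host stem replicate 2 or interface replicate 2. SEOR1, a structural protein of phloem sieve elements, rose by 5.85 ± 0.30 and 5.09 ± 0.35 at chromosome 3, 254885 to 255283 and 254498 to 254782. HSFB4, a heat shock factor with a part in root patterning, had 0 and 2 counts in host stem and 78 and 76 in the interface at chromosome 1, 17225430 to 17226141, a count ratio of 189 (95% interval 51.5 to 1575). Outside the study's list, AT5G49610, an F-box gene, rose by 5.74 ± 0.26 in a coding exon at chromosome 5, 20132322 to 20132435, and had 50 and 88 counts in parasite stem. AT5G03545, a transcript of phosphate starvation, had 1 and 1 counts in host stem and 31 and 25 in the interface in its 5′ UTR at chromosome 5, 894749 to 895274, a count ratio of 68.7 (18.2 to 582).

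**Figure D2:**
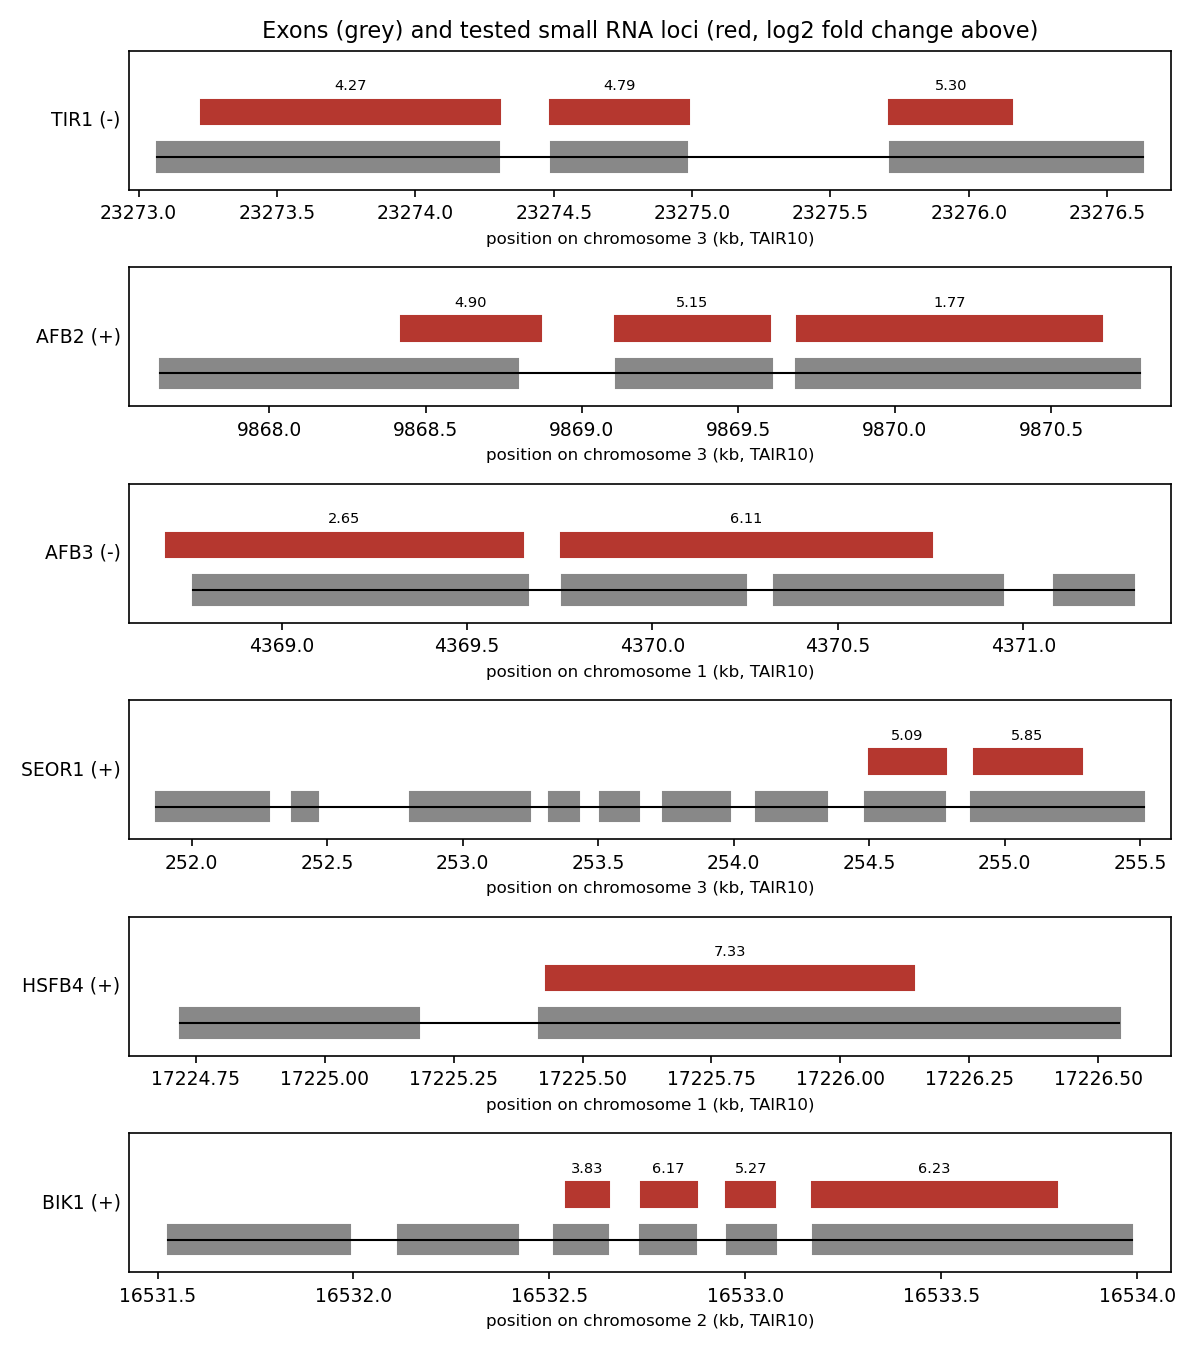
Exons (grey) of the study's 6 genes and their tested small RNA loci (red) along each chromosome (kb, TAIR10), with the log2 fold change of interface against host stem above each locus. All 15 loci lie over exons, with values between 1.77 and 7.33.

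Of the miRNAs of phosphate shortage, 3 of 3 tested loci were higher and 0 lower, with 3 higher when adjusted over the list alone. Their median was 4.42, with an adjusted p = 0.00434 in fry's test (adjusted p = 0.122 with an estimated correlation), and 2 of the 3 had parasite stem counts of at least 10% of their interface counts. MIR399c, which represses the phosphate regulator PHO2, rose by 4.70 ± 0.31 (chromosome 5, 24962497 to 24962588) but had 54 and 38 counts in parasite stem, against 75 and 98 in the interface. MIR827 rose by 2.53 ± 0.19 (chromosome 3, 22122808 to 22122883) with 0 and 0 counts in parasite stem. Of the copper miRNAs, 3 of 5 were higher, 0 lower and 2 not called, and 4 were higher when adjusted over the list alone. Their median was 1.40, or -0.24 when libraries were scaled by the summed totals of both tables, with an adjusted p = 0.0287 in fry's test (adjusted p = 0.173 with an estimated correlation). MIR398b, which represses copper superoxide dismutases, rose by 3.77 ± 0.33 (chromosome 5, 4691034 to 4691248). MIR398c (chromosome 5, 4694706 to 4694798) had 1 and 0 counts in host stem and 17 and 20 in the interface, a count ratio of 90.8 (15.3 to 3684). MIR398a (chromosome 2, 1040948 to 1041032) had a value of 0.67 ± 0.29 and was not called.

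Of the 34 tested loci of developmental miRNAs, 16 were higher, 7 lower and 11 not called, with 20 higher and 8 lower when adjusted over the list alone. Their median was 0.78, or -0.87 with the summed totals, and fry's directional test gave an adjusted p = 0.0721 while its test for change in either direction gave 0.00173. Of these loci, 27 had parasite stem counts of at least 10% of their interface counts, and 3 of the 16 higher loci did not. MIR164b, which represses NAC transcription factors, is 1 of those 3, with a rise of 2.85 ± 0.17 (chromosome 5, 287556 to 287736) and 10 and 8 counts in parasite stem against 273 and 287 in the interface. The parasite cluster clust351, with a head close to miR164, also rose at the interface, so parasite reads may still raise this locus. MIR159a, which represses GAMYB-like factors, rose by 2.08 ± 0.22 (chromosome 1, 27713229 to 27713437) and had 11757 and 14424 counts in parasite stem. MIR166a rose by 1.29 ± 0.24, or -0.36 with the summed totals. Of the auxin miRNAs, 1 of 8 was higher, 3 lower and 4 not called, with 2 and 3 when adjusted over the list alone. Their median was 0.12, their mean -0.34 and the direction of fry's test downward, with an adjusted p = 0.457 for a common direction and 0.00526 for change in either direction. MIR393b (chromosome 3, 20691657 to 20691798) and MIR393a (chromosome 2, 16652104 to 16652232), which both repress TIR1 and its relatives, moved by 0.90 ± 0.19 (-0.76 with the summed totals) and -0.95 ± 0.28, and both lost their call without interface replicate 2. MIR167d, which represses auxin response factors (chromosome 1, 11137556 to 11137578), moved by -2.29 ± 0.27.

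Of the Brassicaceae-specific miRNAs, 0 of 20 were higher, 9 lower and 11 not called, with 14 lower when adjusted over the list alone. Their median was -1.20, with an adjusted p = 0.0287 in fry's test (adjusted p = 0.153 with an estimated correlation). MIR163, which acts on methyltransferase genes, moved by -1.36 ± 0.17 (chromosome 1, 24884327 to 24884414), MIR841b by -1.77 ± 0.17 (chromosome 4, 2183891 to 2184755) and MIR775 by -1.50 ± 0.22 (chromosome 1, 29422216 to 29422568). Of the miRNAs of the silencing pathway (MIR162, MIR168, MIR173 and MIR403), 4 of 6 loci were lower, 0 higher and 2 not called, with 4 lower when adjusted over the list alone. Their median was -1.02, with an adjusted p = 0.0369 (adjusted p = 0.255 with an estimated correlation). MIR168a, which represses AGO1, moved by -1.76 ± 0.17 (chromosome 4, 10578629 to 10578764), and MIR403, which represses AGO2, by -1.36 ± 0.18 (chromosome 2, 19415077 to 19415217). Both tested defence miRNA loci were lower, over all loci and when adjusted over the list alone, with a median of -1.43 and an adjusted p = 0.0287 (adjusted p = 0.173 with an estimated correlation). Of them, MIR846 is also among the 9 lower loci of the Brassicaceae list. MIR472, which acts on NLR immune receptor transcripts, moved by -1.37 ± 0.17 (chromosome 1, 4182108 to 4182410), and its locus, which overlaps an NLR gene, is also 1 of the 2 loci of the NLR list. Both loci of that list were lower, likewise when adjusted over the list alone, with a median of -1.49 and an adjusted p = 0.0287 (adjusted p = 0.173 with an estimated correlation). Of the PPR siRNA loci, 6 of 11 were lower, 0 higher and 5 not called, with 10 lower when adjusted over the list alone. Their median was -1.04, with an adjusted p = 0.00802 (adjusted p = 0.122 with an estimated correlation).

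Of the tasiRNA loci, which give phased siRNAs after a miRNA cut, 1 of 6 was higher, 4 lower and 1 not called, with 1 and 4 when adjusted over the list alone. Their median was -0.85, with an adjusted p = 0.235 for a common direction and 0.00145 for change in either direction. TAS3b rose by 2.96 ± 0.18 (chromosome 5, 20134443 to 20134684) and had 32 and 58 counts in parasite stem, whereas TAS1B moved by -1.29 ± 0.17 (chromosome 1, 18549250 to 18549807) and TAS1C by -1.11 ± 0.18 (chromosome 2, 16537425 to 16538261). The silencing gene list had 1 tested locus, in the 5′ UTR of DCL4 (chromosome 5, 6869217 to 6869759), with a value of -0.07 ± 0.18. Of all 141 tested miRNA gene loci, a list added after the values were seen, 24 were higher, 33 lower and 84 not called, with 28 and 38 when adjusted over the list alone. Their median was -0.06, their mean 0.01 and the direction of fry's test downward, with an adjusted p = 0.969 for a common direction and 0.00145 for either.

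Fragments of structural RNAs, which can follow RNA breakdown or the makeup of a tissue, were lower at part of the tested loci. Their summed counts did not all fall. In host stem and interface, tRNA loci held 8.01% and 10.2% of host-table counts, snoRNA or snRNA loci 2.22% and 2.28%, and rRNA loci 3.22% and 2.00%. The tRNA locus with the highest mean CPM, AT1G07760 (chromosome 1, 2406860 to 2406915), had a value of 0.64 ± 0.23 and was not called. It held 72308 and 95650 of the 246951 tRNA counts in host stem and 52954 and 55162 of the 140209 in the interface. It also had 8617 and 14403 counts in parasite stem, at least 10% of its interface counts. The tRNA share therefore rests largely on this locus, where parasite reads may raise the interface value. Of the tRNA loci, 22 of 68 were lower, 0 higher and 46 not called, with 3 higher and 41 lower when adjusted over the list alone, a median of -0.78 and an adjusted p = 0.00802 in fry's test (adjusted p = 0.122 with an estimated correlation). Of the snoRNA and snRNA loci, 30 of 127 were lower, 3 higher and 94 not called, with 5 higher and 39 lower when adjusted over the list alone, a median of -0.46 and an adjusted p = 0.0369 (adjusted p = 0.161 with an estimated correlation). Of the rRNA loci, 3 of 6 were lower, 0 higher and 3 not called, with 6 lower when adjusted over the list alone, a median of -0.62 and an adjusted p = 0.0287 (adjusted p = 0.173 with an estimated correlation). Among loci that met the rule for naming, the largest falls were in protein-coding and tRNA genes, given as count ratios of host stem over interface with 95% intervals where the interface had 1 to 3 counts. GSTF7, a glutathione S-transferase gene (chromosome 1, 658820 to 659282, coding exon), had a ratio of 20.8 (3.56 to 836), and the 3′ UTR of AT5G15200, a ribosomal protein gene (chromosome 5, 4934957 to 4935268), 17.1 (2.91 to 692). The tRNA genes AT2G36520 (chromosome 2, 15320297 to 15320417) and AT4G26375 (chromosome 4, 13336333 to 13336415) had ratios of 16.3 (2.76 to 659) and 8.42 (2.75 to 41.9). ARFA1E, a small GTPase gene (chromosome 3, 23052243 to 23052433, coding exon), had 10.6 (2.79 to 89.8), and PRXCB, a peroxidase gene (chromosome 3, 18208810 to 18208996, coding exon), 10.3 (3.40 to 51.1). CAT2, a catalase gene, moved by -3.49 ± 0.49 in a coding exon (chromosome 4, 16701633 to 16702413) and an intron of AT3G10815 by -3.35 ± 0.39 (chromosome 3, 3386209 to 3386318). Of these 8 loci PRXCB, CAT2 and AT3G10815 stayed called with each library left out in turn, while the other 5 lost their call without at least 1 library.

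**Figure D3:**
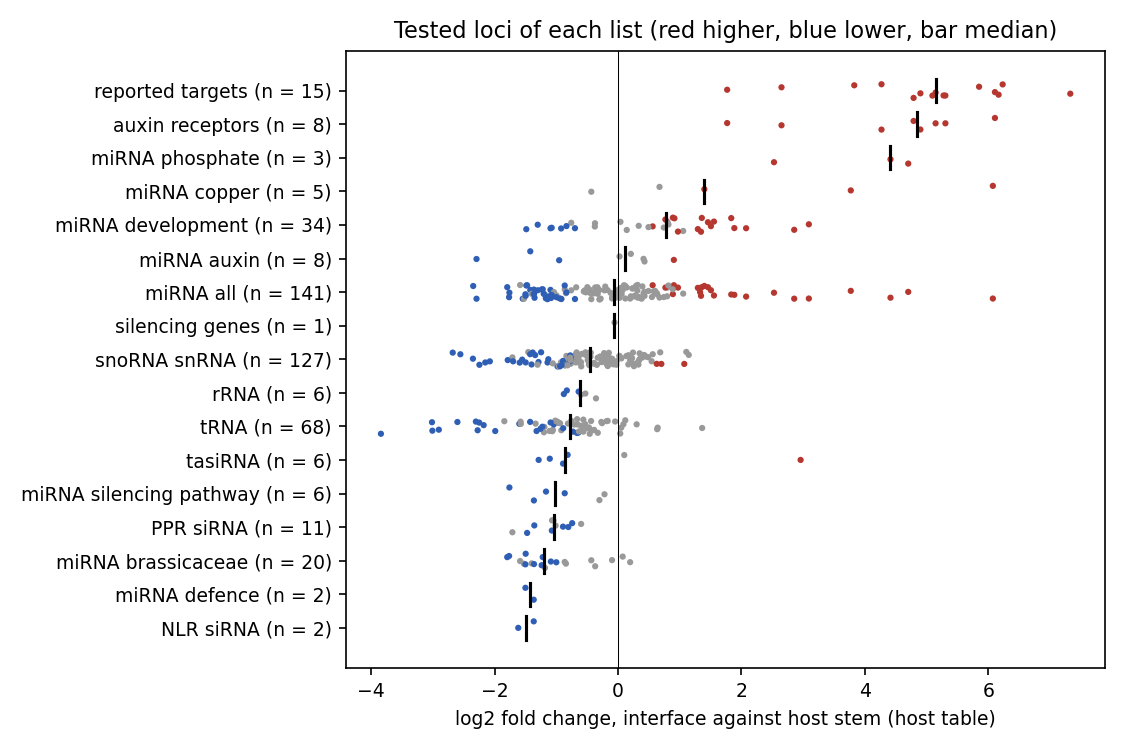
Log2 fold change of interface against host stem (x axis) for each tested locus of each list (y axis, with the number tested), in red where called higher, blue where called lower and grey where not called, with a bar at the median. With libraries scaled by the summed totals of both tables, the medians of the copper, developmental and auxin miRNA lists fell below 0.

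Among the annotation classes, miRNA genes were enriched in both directions, with 24 of 141 higher (odds ratio 10.3, adjusted p = 1.14e-14, Fisher's exact test) and 33 of 141 lower (odds ratio 7.09, adjusted p = 6.69e-15, Fisher's exact test). Only 8 of the 24 higher loci had parasite stem counts below 10% of their interface counts, so parasite reads may raise the others. Parasite RNAs made mainly at the interface would also pass below that cut, so the 8 are not clear of parasite reads. With loci at or above the cut left out, 9 of 84 were higher (odds ratio 6.56) and 24 of 84 lower (odds ratio 7.54). Lower calls were also enriched in tRNA (odds ratio 10.8), snoRNA or snRNA (6.79) and protein-coding loci (226 of 2023, odds ratio 5.01, adjusted p = 3.95e-51, Fisher's exact test). The protein-coding odds ratio was 2.60 (89 of 491) with a minimum count of 50. The largest odds ratio of lower calls was that of rRNA, at 32.5 (3 of 5 loci), or 33.5 (15 of 25) with the rRNA class extended. Loci without annotation, mostly sources of heterochromatic siRNAs in plants, were seldom lower, at 43 of 5051 (odds ratio 0.085, adjusted p = 6.67e-84, Fisher's exact test). They were 5051 of the 8878 tested loci, so the TMM scaling rests largely on them. Their few lower calls, and the enrichment of lower calls in other classes, may partly follow from that. The share of higher among called loci was 33.0% with TMM, 16.1% with table totals (118 higher, 614 lower; median of all loci shifted by -0.16) and 0.42% with the summed totals (36 higher, 8498 lower; shifted by -1.65), so each change is relative to the median host locus. Without interface replicate 1 the calls were 129 higher and 252 lower, without interface replicate 2 they were 111 and 210, and the 12 of 16 lists called by fry became 1 to 5 when a library was left out.

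The comparison of interface with parasite stem asks which parasite small RNAs differ where it feeds. Clusters with heads of 21 or 22 nt, the lengths of plant miRNAs, changed in both directions. Heads of 21 nt held 27.1% of interface and 24.7% of parasite stem counts, and those of 22 nt 21.4% and 21.02%. The 310 clusters of these lengths called higher, selected for that call, made up 25.2% of interface and 2.23% of parasite stem counts, and the 1742 called lower 9.65% and 27.5%. A few clusters held most of the counts of the 310. Of their 665930 interface counts clust1 had 130493 and 136411 and clust2 had 114006. Of their 46901 parasite stem counts clust1 had 9857 and 21369. The higher ones had a median log2 fold change of 3.54, and 218 of them rose at least 4-fold, while the lower ones had a median of -1.48. Clusters of 24 nt, the length of siRNAs that guide DNA methylation, held 42.3% of interface and 37.9% of parasite stem counts. Of these, 1568 were called higher, with a median of 1.64, and those alone made up 6.78% of interface and 2.31% of parasite stem counts, while 519 were called lower, with a median of -1.43, at 3.43% and 8.55%. Of 22024 clusters tested, 2128 were higher and 2846 lower.

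By level, clust1, with a head of 21 nt, rose by 2.70 ± 0.37 (SE, n = 2 per group) from 15767 ± 6542 to 102317 ± 8881 CPM (SD, n = 2), with an adjusted p = 1.74e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. clust2 (CACGAAUAAAGAAAGGCGACUU, 22 nt) rose by 4.57 ± 0.38 and clust4 (CAGCUUGAAAUGUAGUAUCCU, 21 nt) by 5.98 ± 0.40. clust5, clust3 and clust15 moved by -1.98 ± 0.33, -2.82 ± 0.50 and -1.71 ± 0.31, and the parasite stem replicates of clust3 differed 75487 to 15445 in counts. Without interface replicate 2 clust1, clust3, clust5 and clust15 lost their call, while clust2 and clust4 kept it. Among clusters that met the rule for naming, the 8 with the largest rises had 0 counts in both parasite stem libraries, except clust645 with 0 and 1. Against a floor of 3 counts over the group, clust3667 was at least 30.5-fold higher, clust7972 at least 23.9-fold, clust19448 at least 20.2-fold, clust7809 at least 16.0-fold, clust8567 at least 15.03-fold, clust10464 at least 14.3-fold and clust9068 at least 14.04-fold higher. The head of clust9068, which lost its call without interface replicate 2, lies 2 mismatches from miR169d of *Arabidopsis*. clust645 had 242 and 321 counts in the interface, a count ratio of 416 (95% interval 74.4 to 16464).

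By the same rule the 8 with the largest falls, clust4469, clust918, clust5707, clust11431, clust1545, clust8127, clust17580 and clust21681, moved by -4.58 to -4.11, and clust11431, with 3 interface counts, had a count ratio of 22.1 (95% interval 7.13 to 111, parasite stem over interface). In 7 of the 8, all but clust8127, parasite stem replicate 1 had the higher CPM, as in clust4469 (105 against 12.4) and clust918 (658 against 174). Without that library clust4469 stood at -2.40 and clust17580 at -2.84, neither called, clust918 at -3.19 and clust3 at -1.07. Without interface replicate 2 clust4469, clust5707, clust11431, clust8127 and clust17580 were not called. Of their heads, 5 contain GACUCUCGGCAA, which is also in the head of clust15, 2 mismatches from *Arabidopsis* rRNA, and of 42 tested heads with this sequence 0 were higher and 37 lower. In tests added after the values were seen, rRNA-like heads had 1 higher and 341 lower of 575 (odds ratio of lower calls 11.02, adjusted p = 2.06e-156, Fisher's exact test). Of heads of 24 nt 11.7% were higher (odds ratio 1.91 against all other lengths together, adjusted p = 1.35e-38, Fisher's exact test) and of those of 23 nt 15.8% (odds ratio 1.84), while 21 nt (odds ratio 0.554) and 22 nt (odds ratio 0.326) had fewer higher calls. Lower calls were enriched in heads of 20 nt (367 of 598, odds ratio 12.1), 21 nt (odds ratio 3.88) and 22 nt (odds ratio 2.51) and were few in those of 24 nt (519 of 13400, odds ratio 0.109). Heads of 24 nt were 13400 of the 22024 tested clusters, so the TMM scaling rests largely on them. The contrasts between lengths may partly follow from that. These tests also treat clusters as independent, so their p-values may be overstated. Heads that match *Arabidopsis* miRNA genes had 12 higher and 38 lower of 106 (odds ratio of lower calls 3.803, adjusted p = 2.41e-09, Fisher's exact test). Among conserved miRNAs with few host stem counts, chosen after their values were seen, clust351, with a head close to miR164, rose by 2.91 ± 0.33 and clust546, close to miR167, by 3.34 ± 0.36. clust6, identical to miR157, moved by -1.01 ± 0.30, and clust27, close to miR393, had a value of 0.65 ± 0.30 and was not called.

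**Figure D4:**
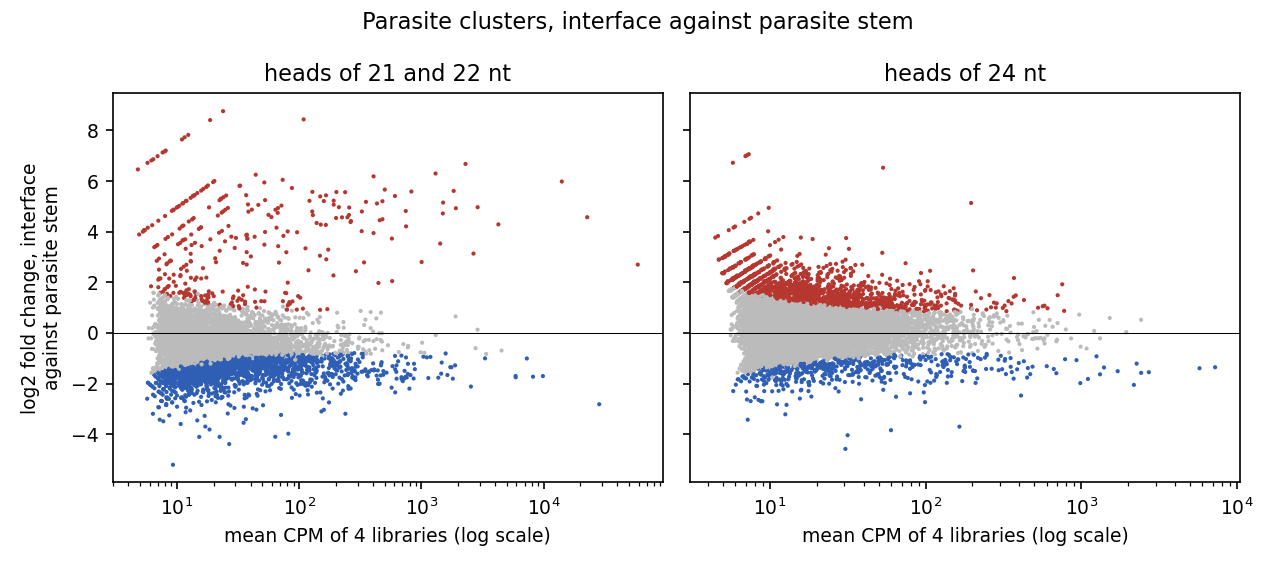
Log2 fold change of interface against parasite stem (y axis) against the mean CPM of the 4 libraries (x axis, log scale) for tested parasite clusters with heads of 21 and 22 nt (left) and of 24 nt (right), in red where called higher, blue where called lower and grey where not called. Higher calls of 21 and 22 nt have a median of 3.54, those of 24 nt a median of 1.64.

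The share of higher among called clusters was 42.8% with TMM and 53.0% with table totals (2666 higher, 2360 lower), which shifted the median of all clusters by 0.11. Without interface replicate 1 the calls were 749 higher and 652 lower, and without interface replicate 2 they were 191 and 8, while the parasite stem replicates differed by more than sampling noise (chi-square per degree of freedom 5.62, against 1.55 in the interface).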

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

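Of the tests in this part, all were chosen after the result they weigh had been seen. Both results below are signals in libraries that the comparisons do not use: counts of parasite clusters in host stem, and counts of host loci in parasite stem.

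Parasite clusters of 21 or 22 nt called higher by at least 4-fold, with heads more than 2 mismatches from *Arabidopsis*, had 8489 and 8610 counts in host stem replicates 1 and 2, or 2.76% of their interface counts (bootstrap interval over clusters 1.70% to 4.08%), and 1.88% without clust1 and clust2. Carry-over or index mixing from the interface would give clusters of like size a like percent, but among clusters of at least 1000 interface counts whose heads lie more than 2 mismatches from *Arabidopsis* the median was 1.55% in 56 called higher and 0.184% in 106 others, a ratio of 8.44 (permutation test, two-sided, p = 1e-05, the smallest that 100000 draws can give). The p-value measures spread over clusters and not between libraries. Clusters such as clust2 and clust45, which pair as a duplex, are not independent, so it may be overstated. The ratio of 8.44 also argues against *Arabidopsis* sequence close to the heads, since such heads were left out, and with all heads it was 7.53. Parasite tissue in the host stem samples would bring 24 nt clusters along, but those called higher by at least 4-fold stood at 0.380% (0.263% to 0.505%). Greater stability of 21 or 22 nt RNAs in traces of parasite material would raise all clusters of these lengths, but those called higher stood at 2.72% (1.59% to 4.11%) and those not called at 0.553% (0.295% to 0.872%), a ratio of 4.93, with those called lower at 0.681%. Movement of parasite small RNAs up the host stem may account for the counts and stays open as an untested hypothesis.

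Unannotated *Arabidopsis* loci with at least 100 interface counts (605 loci) had a median of 14.5% of their interface counts in parasite stem (quartiles 10.06% and 20.8%), and 15.3% when pooled, from 11030 and 12288 counts in parasite stem replicates 1 and 2. Carry-over or index mixing of host RNA would bring host miRNAs along, but the Brassicaceae miRNA loci stood at 0.754% (0.564% to 3.86%) and snoRNA or snRNA loci at 0.305%. Known siRNA sources were also low, with PPR siRNA loci at 1.71% and tasiRNA loci at 3.46% when pooled, whereas protein-coding loci stood at 10.2% when pooled (median 12.5%). Parasite small RNAs of the same sequence cannot be told apart from host siRNAs here: 0.0919% of 24 nt parasite heads lie within 1 mismatch of unannotated *Arabidopsis* sequence, but heads that match exactly number 19 against 284 with 1 mismatch, as if exact matches had been given to the host table, so the low percent excludes nothing. Movement of host siRNAs into the parasite stays open for the same reason, and counts in parasite stem and host stem had a Spearman correlation of 0.475 across loci, which are not independent replicates.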

How the results depend on the processing

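Named loci mostly kept their direction and their side of the threshold. In the host comparison 721 of 789 values under alternatives were unchanged in this sense, 53 were weaker, 9 stronger and 6 reversed, and with a library left out 262 of 302 were unchanged, 32 weaker, 5 stronger and 3 reversed. In the parasite comparison the numbers were 222 of 224 with 2 weaker, and 74 of 87 with 13 weaker. In simulations at the depth, replicate number and spread of these libraries, none of which was varied, 27.8% of 2-fold changes were recovered in the host comparison and 6.98% in the parasite comparison, so many changes of that size would be missed. A lone library in a leave-out fit is assumed to vary like the other group. The planned test of called parasite loci on shared sequences and its stricter filter were not run, since the clusters carry no position, and the sulfate list had 0 tested loci and gave no value.

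The host share without loci counted in libraries of the other species was 100% in host stem, 11.5% in the interface and 0% in parasite stem, where the first and last follow from the choice of loci. Without the 10 loci with the most counts in each table it was 98.3%, 26.2% and 5.96%.

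Host calls (higher, lower) were 118 and 614 with table totals, 36 and 8498 with the summed totals, 124 and 219 with a minimum count of 50, 39 and 17 against a 2-fold change, 52 and 124 with DESeq2, and 99 and 243 at an FDR under 0.01. Without loci shared with the parasite 111 were higher. With a library left out they ran from 111 to 194 and from 210 to 364. Parasite calls were 1040 and 983 with a minimum count of 50, 373 and 312 against a 2-fold change, 534 and 1303 with DESeq2, and 874 and 1399 at an FDR under 0.01. With a library left out they ran from 191 to 2807 and from 8 to 3589. Lists called by direction went from 12 to 0 with an estimated correlation, and to between 1 and 5 with a library left out. The stricter filter and the leave-out fits test other loci or fewer libraries, and beyond that the cause was not tested.

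With the summed totals the direction reversed for MIR166a (-0.36), tRNA AT1G07760 (-1.01), MIR393b (-0.76), MIR408 (-0.24), MIR398a (-0.98) and MIR166f (-0.15). With a library left out MIR398a ran from -0.056 to 1.22 and DCL4 from -0.27 to 0.15. The auxin miRNA list turned upward without shared loci (adjusted p = 0.368) and without interface replicate 1 (adjusted p = 0.921), and its adjusted p ran from 0.340 to 0.921 with a library left out. The list of all miRNA genes, added after the values were seen, turned upward without host stem replicate 1 and without interface replicate 1, with an adjusted p from 0.0995 to 0.921 over the leave-out fits. The odds ratio of snoRNA or snRNA loci among higher calls was 0.883 without shared loci and 0.599 with a minimum count of 50. None of these list and class results was called, and the cause was not tested.

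The groups share replicate numbers with only 2 pairs and no label that ties them, and same-numbered libraries had correlations of deviations of 0.0297 (host table) and -0.0298 (parasite table), so the replicate block was not used in the report. With the replicate block the calls were 260 higher and 476 lower in the host comparison, 2015 and 2645 in the parasite comparison, and 0 lists by direction. The alternatives added after the data were seen gave 1917 higher and 2151 lower without clusters near *Arabidopsis* sequence, and 9 called class tests with the rRNA class extended. Of the head class tests, added likewise, 17 were called, 14 with a minimum count of 50 and 15 without shared clusters.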

Other observations

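The duplex test, the shared-sequence test and the scaling tests in this part were chosen after the results they weigh had been seen, and the site search was set down before its own result but on genes known to have risen.

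Many interface-enriched parasite clusters came in pairs. Of 298 heads of 21 or 22 nt that were called higher and searched, 107 (35.9%) had a partner among heads of their length that would form a duplex with 3′ overhangs of 2 nt, against 400 of 4452 heads not called (8.98%) and 162 of 1702 heads called lower (9.52%). The odds ratio of higher against not called was 5.67 (Fisher's exact test, two-sided, p = 8.63e-34), and with partners reversed the percents were 4.03% and 2.90%. Abundance was not matched: the 164 higher clusters of 21 nt held 423230 interface counts and the 1752 not called 147350. Some heads also share a partner, such as clust31, clust278 and clust529 with clust351, so heads are not independent. The reversed control addresses neither point, so the p-value and the contrast may be overstated. Pairs chosen after their values were seen include clust2 with clust45, clust19 with clust325, clust25 with clust57 and clust39 with clust28, and the clust39 pair had 7628 and 7545 interface counts. These pairs are in line with miRNA and miRNA star duplexes, a hypothesis that a genome with hairpin precursors would test.

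The rise of small RNAs at host genes may follow cleavage by such parasite RNAs, a hypothesis for which only predicted sites were searched. Cleavage itself was not tested. Of 40 genes with a protein-coding locus called higher, 10 (25%) held a site for a 21 or 22 nt head called higher, against 34 of 1613 genes with none higher (2.11%), an odds ratio of 15.5 (Fisher's exact test, p = 2.9e-08). Without the study's genes it was 6 of 34 genes (odds ratio 9.95, p = 0.000114 by Fisher's exact test), random heads that were not called gave at most 5 genes (permutation p = 0.0001, the smallest that 10000 draws can give), and 10 genes were left after 4 sites that may come from variants of host reads were taken out. Parasite sequence counted at the host loci stays open: 30.8% of the 52 higher protein-coding loci (exact 95% interval 18.7% to 45.1%) had parasite stem counts of at least 10% of their interface counts, but parasite clusters of 21 or 22 nt called higher hold 7.04% themselves, so parasite RNAs made mainly at the interface would pass below that cut. Scaling is argued against for the study's loci, of which 14 of 15 were still called higher with the summed totals, but it stays open for the other 37 protein-coding loci, of which 11 (29.7%) kept their call and 17 were called lower. The search covers 10 of 40 genes and SEOR1 and HSFB4 had no site at this score, so other sources stay open.

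Sites chosen after they were seen lie in coding sequence, some of them at or next to loci that rose and others away from them, such as those in AT4G11900 (2265 bases away) and AT5G60570 (181 bases), and 1 of 2 in AT5G15790 (403 bases). The head of clust39 (UGUACCAUGAUUUGUAGACGAG) has sites in AFB2 (chromosome 3, 9868420 to 9868441, score 2), in AFB3 (chromosome 1, 4370681 to 4370702, score 3.5) and in AT5G49610 (chromosome 5, 20132416 to 20132437, score 2.5). clust382, with a similar head, has a site in TIR1 (chromosome 3, 23276067 to 23276088, score 2). The end of the AT5G49610 site is also the start of the head of clust28, the duplex partner of clust39. Reads of clust28 may therefore be counted at that host locus. In BIK1, clust71 has a site at chromosome 2, 16532597 to 16532618, and clust606 at 16533045 to 16533066, both with a score of 1. The head of clust351, close to the conserved miR164, has a site in AT3G12977 (chromosome 3, 4145631 to 4145651, score 1). The host's own miRNAs were not searched, and the host locus MIR164b rose by 2.85 ± 0.17, though parasite reads may add to it. The site may therefore serve host miR164 as well, and this gene, counted among those with a site, cannot be assigned to the parasite RNA.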
